A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

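RNA was measured by sequencing in 4 libraries of the ESS1 degron strain, 2 from cultures given DMSO and 2 from cultures given 2 mM IAA for 3 h, grouped by the treatment in the labels. Total RNA was extracted with a column kit and made into libraries with a directional (strand-keeping) kit, per the labels' protocols. Whether RNA was selected for poly(A) tails or depleted of ribosomal RNA, and whether counting used the strand, is not given in the sources used here, so reads of antisense neighbours may be mixed. The authors deposited RSEM expected counts per gene, whose values need not be whole, and FPKM values (counts scaled by gene length and library total) in a second table. The submitters' processing notes name FastQC 0.11.9, Trimmomatic, STAR 2.7.10a, SAMtools 1.10, RSEM 1.3.3, DESeq2 and genome build R64, with no order or role. RSEM divides reads that match several loci among them, so near-identical genes share reads. Genes with a decimal in the estimated count of at least 1 library (428 of 6459 rows) were marked as sharing reads. The counts are given to 2 decimals, and a value was taken as whole only where it equalled its rounded value exactly (tolerance 0), so a share that rounds to a whole number is missed. About 94% of the values, with those at 0 included, were whole in each library.

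Library totals were about 26046700 and 27609300 estimated counts in DMSO and 33589100 and 33625200 in IAA, so IAA libraries were deeper. Ribosomal DNA took 5.26% and 4.87% of the counts in DMSO and 7.02% and 6.16% in IAA. Transposon genes took 6.42% in both DMSO libraries and 7.37% and 7.33% in IAA. Replicates differed by more than sampling noise (chi-square per degree of freedom 6.40 in DMSO and 19.6 in IAA), so all 4 libraries were kept as separate samples. The design text of the series calls them biological replicates. All 299 tRNA genes were at 0 in every library, and 441 rows in all were.

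Gene names, positions and neighbours came from the RefSeq annotation of R64, in which 6456 of the 6459 row names were found. Gene models there have coding lengths, since 99.2% are multiples of 3. Expected counts were rounded to whole numbers. Tests were run in R 4.3.3 with edgeR 4.0.16: low counts were removed with the default filterByExpr, which left 5799 genes, libraries were scaled with TMM (factors 1.04, 1.04, 0.960 and 0.969), and glmQLFit and glmQLFTest compared IAA with DMSO without further covariates. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± SD of 2 libraries. On counts simulated from these means and library sizes, with 200 genes changed, edgeR recovered 60% of the genes changed 1.2-fold and 100% of those changed 1.5-, 2- or 4-fold over 5793 tested genes, with 11 false calls among 191. The changed genes were picked above a minimum mean count, so recovery among genes with low counts was not tested. They were also far fewer than the genes called in the data.

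Before the data were examined, 37 gene lists were fixed, covering functions tied to Ess1, telomeres, the cell cycle, stress, nutrients and noncoding RNA. The 36 lists with at least 4 tested members were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Of these, 15 passed. With the correlation estimated from the residuals 0 passed, while 1 had an unadjusted p under 0.05, and fry, which asks only whether a list's genes move one way, passed 20. In the simulated data a truly raised list also failed with an estimated correlation (camera adjusted p = 0.114). Its genes were drawn independently, so it cannot tell low power from real correlation between genes as the reason that 0 passed. Estimated correlations in the data were 0.51 for ribosome biogenesis and 0.78 for ribosomal proteins. They lay below the preset 0.01 for genes within 20 kb of a chromosome end (0.0018), meiosis genes (-0.0022), COS genes (-0.059) and PAU genes (-0.065). For the lists below 0.01 this argues against correlation between genes as the reason that they did not pass. Counts of changed genes are given over all tested genes and adjusted over the list alone. The genes named in the text followed a rule set in advance: ESS1, the 12 largest rises and 12 largest falls among called genes with a mean of at least 10 CPM and no overlap between groups, without transposon and repeated telomeric families, and in each list up to 4 members with the lowest adjusted p, or up to 2 where the list did not pass. Genes named after their values were seen are said to be so.

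Alternatives set in advance were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), stricter thresholds, each library left out in turn (the lone library of its group then being assumed to vary like the other group), the replicate number as a block, other set tests, other distances from a chromosome end or snoRNA, and the end list without gene copies. Alternatives added after seeing the data were a 1.5-fold limit, removal of ribosomal DNA and transposon rows, removal of intronic snoRNAs, the end list without members of any other list, and the end list without gene copies under an estimated correlation or fry. Expression-matched random lists were drawn 10000 times from 20 bins of mean expression. Trends with expression, coding length and GC content were fitted with natural splines over 5724 coding genes and explained 6.43% of the variance of the log2 fold change. Figures were drawn with matplotlib 3.10.9.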

Results

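RNA-seq was carried out on budding yeast (Saccharomyces cerevisiae) of the BY4741 background in which the prolyl isomerase Ess1 carries an auxin-inducible degron, a tag that leads to breakdown of the protein once auxin is added. Ess1 acts on the C-terminal domain of RNA polymerase II. The strain also expressed the plant receptor OsTIR1, which the degron needs. Mid-log cultures received DMSO, the control, or 2 mM of the auxin indole-3-acetic acid (IAA) for 3 h. Each treatment had 2 libraries, described by the submitters as biological replicates. Estimated counts summed to about 26046700 and 27609300 in the DMSO libraries and to about 33589100 and 33625200 in the IAA libraries. Replicates correlated at r = 0.996 in DMSO and r = 0.997 in IAA over log2 values of all tested genes, against at most r = 0.977 between groups. Ess1 protein was not measured in these files, and the comparison asks how the transcriptome differs after auxin treatment of this strain.

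ESS1 mRNA itself was 1.4-fold higher in IAA, from 5.23 ± 0.117 to 7.31 ± 0.863 CPM (TMM-scaled, mean ± SD, n = 2), with a log2 fold change of 0.48 (SE 0.127, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0109). The gene lies on chromosome X, 466521 to 467033, of build R64. The degron acts on the protein, so its transcript does not report depletion. In IAA, most genes tested in lists of the stress response, glucose-repressed genes and glycolysis were higher, together with many snoRNAs, and most ribosome biogenesis and G1/S genes were lower. In total 3380 of 5799 tested genes changed at an adjusted p under 0.05, 1666 of them higher and 1714 lower in IAA. Changes were mostly small: 559 genes changed at least 1.5-fold (399 higher, 160 lower) and 179 at least 2-fold (151 higher, 28 lower). Genes higher in IAA made up 49.3% of the calls with TMM scaling, 31.1% with library size scaling, which moved the median of all genes by -0.10 on the log2 scale, and 34.4% in the FPKM values on the log2(FPKM + 1) scale. All samples came from the degron strain, so the comparison does not separate loss of Ess1 from other effects of IAA.

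Among genes with a mean of at least 10 CPM, leaving out transposon genes and the repeated YRF1, COS, PAU, DAN and TIR families, the largest rises began with CTO1 (chromosome III, 141217 to 142170), which increased from 20.2 ± 0.29 to 162 ± 25.8 CPM (mean ± SD, n = 2), or 8.03-fold. PDR12, a plasma membrane exporter of weak organic acids, increased 4.85-fold, from 93.4 ± 9.23 to 453 ± 40.1 CPM (n = 2). USE1, which encodes a SNARE protein of the endoplasmic reticulum, rose 4.2-fold and DIN7, a mitochondrial nuclease, 3.55-fold. The snoRNA SNR82 rose 3.43-fold, YHR033W 3.32-fold and the methionine permease gene MUP3 3.07-fold. Smaller rises were seen for INO1, which encodes inositol-3-phosphate synthase (2.86-fold), for FLX1, a mitochondrial FAD transporter (2.72-fold), and for the DNA polymerase gene POL4 (2.66-fold). POL4 (chromosome III, 139185 to 140933) lies next to CTO1 on the same strand, and whether their rises are separate was not tested. TMA10 (2.65-fold) and GND2, a 6-phosphogluconate dehydrogenase (2.51-fold), completed the 12 strongest rises. Their log2 fold changes lay between 1.33 (SE 0.0973) and 3.01 (SE 0.107), with edgeR adjusted p between 2.87e-06 and 3.38e-05, and both IAA libraries exceeded both DMSO libraries in each.

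By the same rule, the largest falls were smaller than the largest rises. YGL108C decreased 2.37-fold, from 22.1 ± 1.01 to 9.32 ± 1.38 CPM (n = 2), and YNL040W 2.13-fold, from 80.2 ± 0.777 to 37.6 ± 1.32 CPM (n = 2). LSO2 fell 2.07-fold, VPS60, a factor of the ESCRT pathway, 2.05-fold and GON7, a subunit of the KEOPS complex that modifies tRNA, 2.03-fold. YHB1, the flavohemoglobin that detoxifies nitric oxide, fell 1.98-fold, from 691 ± 12.4 to 348 ± 4.48 CPM (n = 2). The ferric reductase gene FRE4 (1.95-fold), YGR035C (1.9-fold), PAM16, part of the mitochondrial import motor (1.88-fold), and the ribosome assembly gene MAK16 (1.87-fold) also fell. YFL068W (2.44-fold) and TAR1 (2.27-fold), which lies antisense to the 25S ribosomal RNA, had estimated counts with decimals, a sign of reads shared with other loci, and are uncertain. The edgeR adjusted p for these 12 genes ranged from 4.35e-06 to 2.28e-04, and both IAA libraries lay below both DMSO libraries in each.

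**Figure D1:**
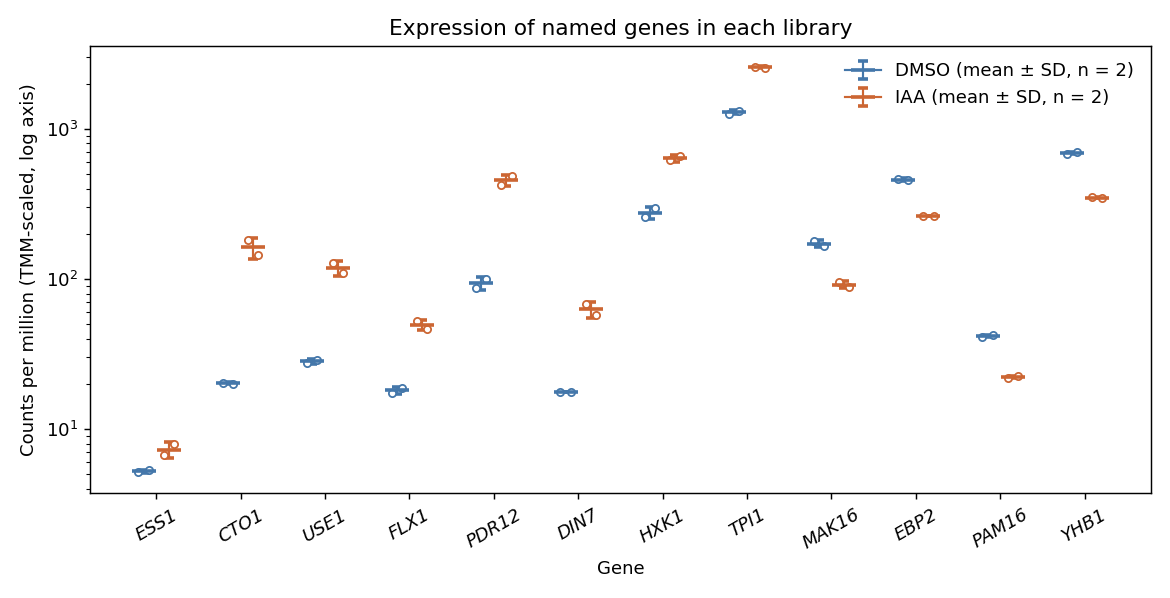
Expression of 12 named genes, with the gene on the horizontal axis and CPM on a logarithmic vertical axis; open points are single libraries, and the wide marks with error bars are the mean ± SD of the 2 DMSO (blue) and 2 IAA (orange) libraries. CTO1 moved from 20.2 ± 0.29 to 162 ± 25.8 CPM and YHB1 from 691 ± 12.4 to 348 ± 4.48 CPM.

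Most genes for making ribosomes fell, while more ribosomal protein genes rose than fell. Among 72 ribosome biogenesis genes, 59 fell and 2 rose, with a median log2 fold change of -0.27 (camera adjusted p = 1.11e-09 at a preset correlation; adjusted p = 0.567 with an estimated correlation). The counts were 61 and 2 when adjusted over the list alone. RRP8 fell 1.85-fold, EBP2 1.75-fold and NOP14 1.65-fold. Of 136 ribosomal protein genes, 71 rose and 19 fell (72 and 19 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 1.59e-04; adjusted p = 0.694 with an estimated correlation). With library size scaling the median of ribosomal protein genes was 0.07 and that of ribosome biogenesis genes -0.37. The ribosomal protein list was not called with fry (adjusted p = 0.113). RPS7A rose 1.64-fold and RPS3 1.53-fold, while RPS26B fell 1.59-fold. RPL2B rose 1.68-fold, but its reads are shared with its near-identical copy.

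Genes of carbon use and of the general stress response were higher in IAA. Of 40 genes that many stresses induce, 33 rose and 2 fell (34 and 2 adjusted over the list alone; median log2 fold change 0.50, camera adjusted p = 7.50e-07; adjusted p = 0.567 with an estimated correlation). YGP1, a secreted glycoprotein, rose 2.21-fold and the glycogen phosphorylase gene GPH1 2.17-fold. Among 31 glucose-repressed genes, 27 rose and 1 fell, the same numbers as adjusted over the list alone (median 0.56, camera adjusted p = 9.61e-07; adjusted p = 0.506 with an estimated correlation). The hexokinase gene HXK1 rose from 276 ± 26.4 to 639 ± 33.3 CPM (n = 2), or 2.31-fold. The aldehyde dehydrogenase gene ALD4 rose 2.02-fold and the glucose transporter gene HXT2 1.72-fold. Of 20 glycolysis genes 16 rose and 0 fell, also when adjusted over the list alone (median 0.40, camera adjusted p = 3.35e-05; adjusted p = 0.506 with an estimated correlation). TPI1, triose phosphate isomerase, rose 1.99-fold and the phosphoglycerate kinase gene PGK1 1.91-fold. Once trends with expression, coding length and GC content over all coding genes were removed, the median was 0.01 for glycolysis and 0.31 for glucose-repressed genes. Against random lists matched on expression alone, the uncorrected medians of both lists lay at the 100 percentile.

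Genes of nitrogen and sulfur supply also rose. Of 28 genes under nitrogen catabolite control, 16 rose and 2 fell (17 and 2 adjusted over the list alone; median 0.34, camera adjusted p = 5.40e-04; adjusted p = 0.506 with an estimated correlation). GDH2, a glutamate dehydrogenase, increased 1.9-fold, the urea permease gene DUR3 1.65-fold and CAR2 1.7-fold. Of 24 genes of sulfur amino acid synthesis and uptake, 14 rose and 1 fell, likewise when adjusted over the list alone (median 0.21, camera adjusted p = 0.00801; adjusted p = 0.506 with an estimated correlation). STR3 rose 2.32-fold and MET3, which encodes ATP sulfurylase, 1.37-fold.

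Cell cycle genes of G1 and of the M/G1 boundary fell, and genes of the pheromone response and meiosis rose. Of 27 G1/S genes, 20 fell and 0 rose, the same numbers as adjusted over the list alone (median -0.27, camera adjusted p = 1.04e-04; adjusted p = 0.506 with an estimated correlation). The G1 cyclin gene CLN2 fell 1.4-fold, the cohesin gene MCD1 1.66-fold and YOX1 1.45-fold. Of 22 M/G1 genes, 15 fell and 2 rose, also when adjusted over the list alone (median -0.27, camera adjusted p = 0.00124; adjusted p = 0.567 with an estimated correlation). EGT2 fell 1.45-fold and SIC1, an inhibitor of the cyclin-dependent kinase, 1.34-fold. Of 18 pheromone response genes, 11 rose and 0 fell, as when adjusted over the list alone (median 0.28, camera adjusted p = 0.00242; adjusted p = 0.506 with an estimated correlation). PRM5 rose 2.36-fold, PRM1 2.23-fold and FUS1 2.01-fold. Of 28 meiosis genes, 16 rose and 1 fell, as when adjusted over the list alone (median 0.43, camera adjusted p = 5.40e-04; adjusted p = 0.506 with an estimated correlation). MER1, a meiotic splicing factor, rose 2.27-fold and HOP1 1.66-fold, from levels of 5 and 12.6 CPM in DMSO. The median of the meiosis genes was 0.23 once the same trends were removed.

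**Figure D2:**
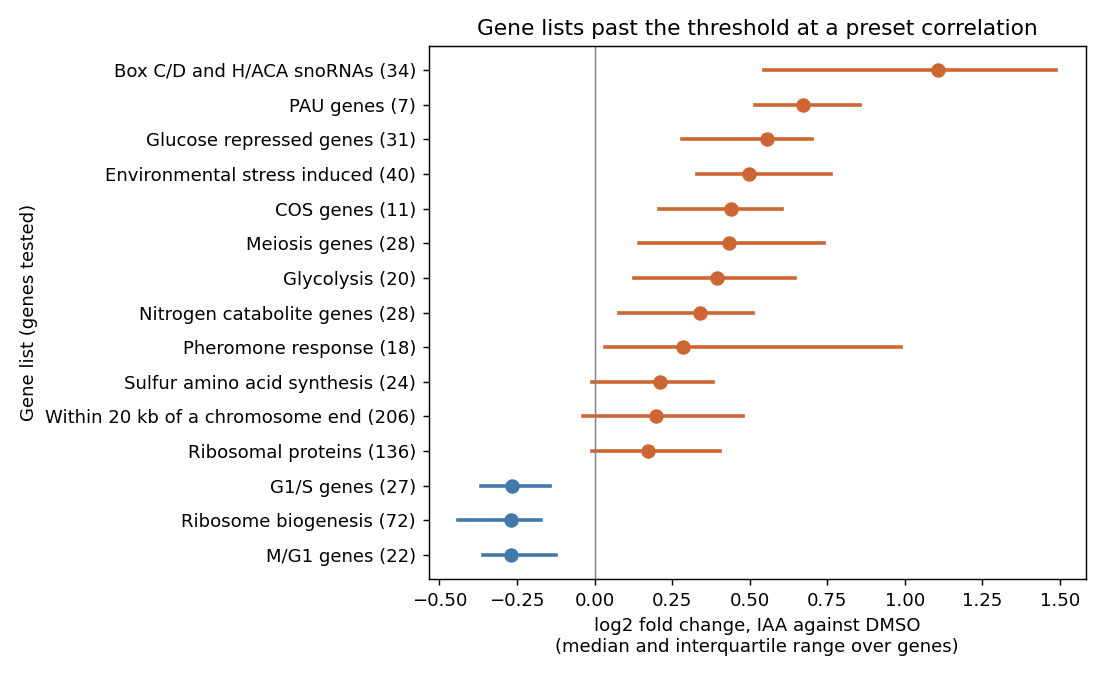
Log2 fold change of IAA against DMSO (horizontal axis) for the 15 gene lists past the threshold at a preset correlation (vertical axis, with the number of genes tested); points are medians over genes and lines interquartile ranges. The medians run from -0.27 in the M/G1 genes to 1.11 in the snoRNAs, and 12 of the 15 lie above 0.

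The series concerns TERRA, the RNA transcribed from telomeres, and genes near chromosome ends were examined for that reason; TERRA itself was not analysed here. Of 206 tested genes within 20 kb of an end, 79 rose and 20 fell (78 and 20 adjusted over the list alone), with a median log2 fold change of 0.20 (camera adjusted p = 5.40e-04; adjusted p = 0.506 with an estimated correlation). That was 38.3% higher and 9.71% lower, against 28.4% and 30.2% of the other 5582 nuclear genes. Without multi-copy families and genes with shared reads, 98 genes had a median of 0.13, and 36 rose and 10 fell (camera adjusted p = 0.00948; adjusted p = 0.506 with an estimated correlation). This median lay at the 93 percentile of random lists matched on expression, and that of the 108 members with copies or shared reads (0.24) at the 99.13 percentile. Once trends with expression, coding length and GC content were removed, the median of the 200 coding members went from 0.20 to 0.04. Nearest the ends, of 42 genes within 5 kb 15 rose and 7 fell, with a median of 0.09. NFT1, a transporter gene, rose 2.37-fold, from 156 ± 0.457 to 370.2 ± 25.4 CPM (n = 2), and its neighbour YKR104W 2.31-fold. YER190C-B had 18 ± 4.14 CPM in DMSO (n = 2) and no read in IAA, at least 194-fold lower against a floor of 3 counts per library, which covers counting error only. It overlaps a Y' helicase gene on the opposite strand and shares reads with copies, so this value is uncertain.

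**Figure D3:**
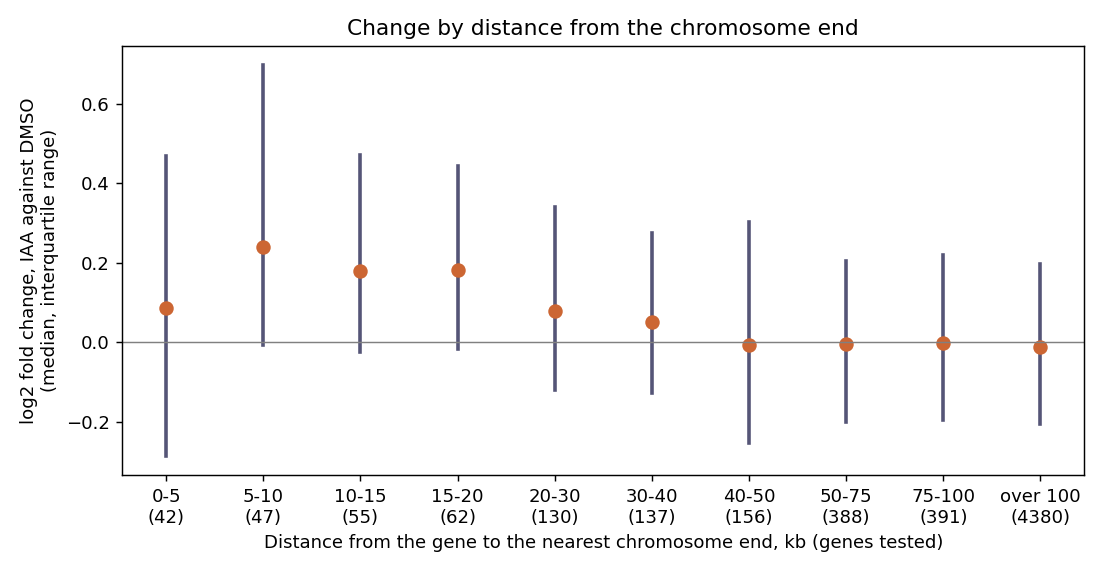
Log2 fold change of IAA against DMSO (vertical axis) by distance from the gene to the nearest chromosome end in kb (horizontal axis, with the number of genes tested); points are medians over genes and lines interquartile ranges. Medians were 0.09 at 0 to 5 kb, 0.24 at 5 to 10 kb, 0.18 at 15 to 20 kb and -0.01 beyond 100 kb.

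Repeated gene families were tested as lists of their own. Of 11 COS genes, 7 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.44, camera adjusted p = 0.0191; adjusted p = 0.506 with an estimated correlation). COS9, whose counts were whole, rose 1.36-fold, and COS6, which shares reads, 1.67-fold. With reads of all 12 rows named COS and a number summed to 1 value, the sum rose 1.37-fold (edgeR adjusted p = 6.11e-05). These rows go beyond the 11 of the list and were picked by name alone. Whether all of them belong to the family was not checked. Of 7 tested PAU genes, 2 rose and 0 fell, as when adjusted over the list alone (median 0.67, camera adjusted p = 0.00242; adjusted p = 0.506 with an estimated correlation). The PAU median lay at the 70.4 percentile of random lists matched on expression, whose own median was 0.46, and was 0.18 once trends with expression, coding length and GC content were removed. With reads of all 24 PAU rows summed to 1 value, the family rose 1.54-fold, from 9.77 ± 0.161 to 15 ± 1 CPM (n = 2 each; edgeR adjusted p = 5.28e-04). With no filter on low counts the PAU list was not past the threshold (camera adjusted p = 0.0697). PAU2, 63727 bp from the nearest chromosome end, rose 1.91-fold from 1.15 CPM, with an edgeR adjusted p of 0.0508 without DMSO replicate 2. With a library left out, its group holds 1 library, which is assumed to vary like the other group. All 8 tested YRF1 genes, the helicase genes of the Y' element next to telomeres, had shared reads. RSEM gave 6 of them higher and 2 lower counts, also when adjusted over the list alone, and the list was not past the threshold (median 0.54, camera adjusted p = 0.0871). It passed without DMSO replicate 1 (adjusted p = 0.0259) and without DMSO replicate 2 (adjusted p = 0.0364). Summed to 1 value, YRF1 reads rose 1.17-fold, from 1243 ± 9.44 to 1453 ± 46.4 CPM (n = 2 each; edgeR adjusted p = 0.00196).

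Reads of small nucleolar RNAs, which guide modification of ribosomal RNA, rose as a group. Of 34 tested box C/D and H/ACA snoRNAs, 23 rose and 2 fell (24 and 2 adjusted over the list alone; median 1.11, camera adjusted p = 4.04e-07; adjusted p = 0.506 with an estimated correlation). SNR33 rose 6.11-fold and SNR63 3.71-fold, from 1.96 and 3.38 CPM in DMSO. Most snoRNAs had under 10 CPM. All snoRNA rows together took only 0.0171% and 0.0156% of the counts in DMSO and 0.0256% and 0.0225% in IAA. Whether these few reads came from mature snoRNAs was not tested. With a filter at a mean of 10 CPM only 6 were left, of which 4 rose and 2 fell, and the list was not past the threshold (median 0.74, interquartile range -0.15 to 0.97, against 1.11, 0.54 to 1.49, for the 34; camera adjusted p = 0.194). Genes that start within 1000 bp downstream of a snoRNA on the same strand were not past the threshold as a group. Of 32 such genes, 10 rose and 6 fell, as when adjusted over the list alone (median 0.04, camera adjusted p = 0.185). 4 genes of this list rose at least 2-fold, namely CTO1 193 bp beyond SNR33, YDR042C 398 bp beyond SNR47, USE1 286 bp beyond SNR82 and FLX1 148 bp beyond SNR68. YDR042C, named after its value was seen, rose 8.25-fold, from 1.49 ± 0.0354 to 12.3 ± 3.38 CPM (n = 2).

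**Figure D4:**
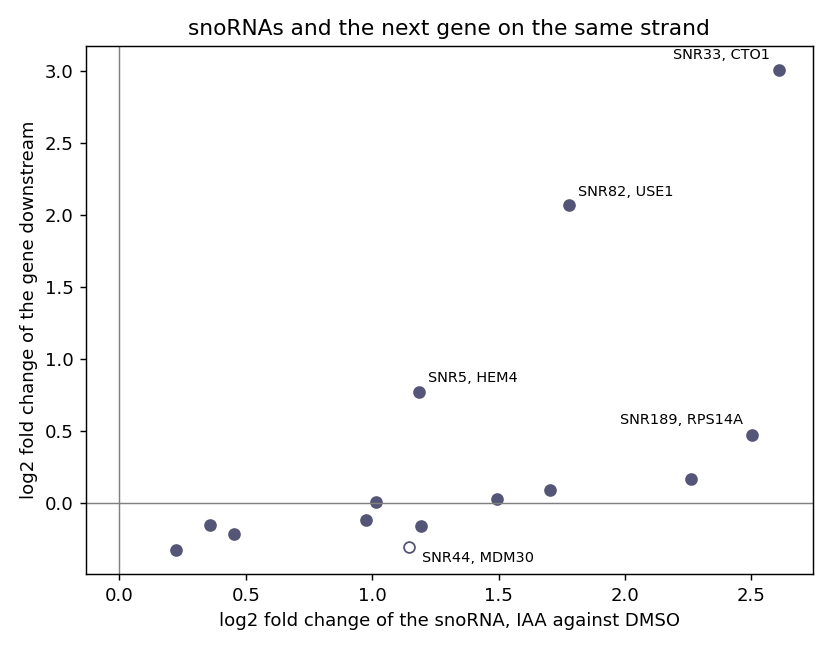
Log2 fold change of a snoRNA (horizontal axis) and of the gene downstream within 1000 bp on the same strand (vertical axis), both IAA against DMSO, for the 14 pairs in which both were tested; each point is 1 pair, and the open point is the only snoRNA inside an intron, SNR44 with MDM30 (1.15 and -0.30). The pairs SNR33 with CTO1 (2.61 and 3.01) and SNR82 with USE1 (1.78 and 2.07) lie at the upper right.

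Other lists held changed genes without passing as a group with camera, and their counts were the same adjusted over the list alone unless stated. Among factors that act on the polymerase C-terminal domain or end transcription, 3 rose and 12 fell of 26 (adjusted p = 0.136). SPT5, an elongation factor, fell 1.25-fold and the kinase gene SGV1 1.37-fold. Among genes under early termination, 7 rose and 1 fell of 10 (adjusted p = 0.0587), and the CTP synthase gene URA8 rose 1.41-fold. Among other prolyl isomerases, 8 rose and 6 fell of 14 (adjusted p = 0.623), with CPR1 1.73-fold and FPR1 1.67-fold higher. Among telomere maintenance genes, 6 rose and 8 fell of 31 (adjusted p = 0.412). PAF1, of the elongation complex of that name, fell 1.68-fold, and TLC1, the telomerase RNA, rose 1.36-fold, from 106 ± 1.2 to 144 ± 8.53 CPM (n = 2; edgeR adjusted p = 2.39e-04). Among histone genes, 5 rose and 2 fell of 8 (adjusted p = 0.134), and HTA1 rose 1.81-fold. Among DNA damage genes, 5 rose and 2 fell of 18, or 4 and 1 adjusted over the list alone (adjusted p = 0.254), and the ribonucleotide reductase gene RNR4 fell 1.38-fold. Among genes of the weak acid and drug response, to which PDR12 belongs, 12 rose and 5 fell of 28, or 16 and 5 adjusted over the list alone (adjusted p = 0.0587). For heat shock proteins, 4 rose and 12 fell of 27 (adjusted p = 0.181), with HSP10 1.86-fold higher and STI1 1.4-fold lower. For the proteasome, 15 rose and 3 fell of 33, or 14 and 3 adjusted over the list alone (adjusted p = 0.0566), and for the respiratory chain, 19 rose and 6 fell of 36, or 20 and 8 adjusted over the list alone (adjusted p = 0.0624). For cell wall integrity, 12 rose and 1 fell of 24 (adjusted p = 0.0587), and BGL2, a glucanase, rose 1.68-fold.

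For amino acid synthesis under Gcn4, 14 rose and 3 fell of 33 (adjusted p = 0.0587), and TRP5 rose 1.39-fold. For the phosphate regulon, 2 rose and 10 fell of 18 (adjusted p = 0.0871), and for the iron regulon, 6 rose and 6 fell of 25, or 6 and 5 adjusted over the list alone (adjusted p = 0.526). SPL2 fell 1.84-fold and the cell wall mannoprotein gene FIT2 1.46-fold. For inositol and phospholipid genes, 7 rose and 3 fell of 17 (adjusted p = 0.257), and for ergosterol synthesis, 10 rose and 8 fell of 26 (adjusted p = 0.602). For G2/M genes, 1 rose and 7 fell of 20 (adjusted p = 0.284), for DAN and TIR mannoproteins, 2 rose and 0 fell of 7, or 1 and 0 adjusted over the list alone (adjusted p = 0.577), and for a-specific genes, 2 rose and 0 fell of 6 (adjusted p = 0.142). The list of alpha-specific genes had fewer than 4 tested members. Leaving out 1 library, where the lone library of its group is assumed to vary like the other group, took some of these lists past the threshold. Without DMSO replicate 1 this was the proteasome (camera adjusted p = 0.0481). Without DMSO replicate 2 it was the weak acid (0.0317), respiratory (0.0478) and cell wall (0.0418) lists. Without IAA replicate 1 it was the phosphate (0.0129), weak acid (0.0374) and cell wall (0.00254) lists. Without IAA replicate 2 it was the early termination (0.0284), respiratory (0.0305) and proteasome (0.0284) lists.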

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

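The 1.5-fold limit, the removal of ribosomal DNA and transposon rows, the removal of intronic snoRNAs, the end list without members of other lists, and the end list without gene copies under an estimated correlation or fry were chosen after the data were seen. The count of changed genes was 3380; it lay between 2849 with DESeq2 and 3632 with library size scaling over the other scalings, filters, tools and FPKM values, between 2577 and 3406 with each library left out (its group then holds 1 library, assumed to vary like the other group), and was 2457 at an adjusted p under 0.01. Every gene called both there and in the original test kept its direction. Requiring at least a 2-fold change left 179 genes (151 higher, 28 lower) and at least 1.5-fold 559 (399 higher, 160 lower), by construction. The log2 fold change of ESS1 was between 0.36 and 0.60 with each library left out. The number of lists past the threshold was 15, between 17 and 19 with a library left out, 19 with library size scaling, 14 with no filter on low counts (without PAU genes), 20 with a mean of at least 10 CPM, and 0 with an estimated correlation. The 20 held 13 of the 15; snoRNAs were lost, too few PAU genes were left to test, and the early termination (0.0458), Gcn4 (0.0218), phosphate (0.0264), weak acid (0.0329), respiratory (0.0458), cell wall (0.0448) and proteasome (0.0218) lists passed as well (camera adjusted p in brackets). Library size scaling kept the 15 and added the YRF1 (0.0195), weak acid (0.0471), respiratory (0.0192) and cell wall (0.0471) lists. The list within 20 kb of a chromosome end kept its median of 0.20 but was not called with an estimated correlation (adjusted p = 0.506), a setting with few residual degrees of freedom. Without gene copies (median 0.13) it was not called there either (adjusted p = 0.506), but was with fry (adjusted p = 0.0182). It was called within 10 kb (median 0.22), 30 kb (0.14) and 50 kb (0.08), and without members of any other list (0.17, adjusted p = 0.00804). With library size scaling the list within 20 kb was called with a lower median of 0.09. Genes downstream of a snoRNA (median 0.0361) were called with fry (adjusted p = 0.0243), which does not compare them with other genes, and by none of the distances tried with camera. fry called 14 of the 15 lists and not ribosomal proteins (adjusted p = 0.113). The labels do not say that equal replicate numbers share a culture or day, and deviations from the group means correlated at r = 0.239 over 2 pairs, too few to settle it, so samples were not treated as paired. With the replicate number as a block 3708 genes were called, including all 3380, the list of genes under early termination passed (adjusted p = 0.0454) beside the 15, and ESS1 had a log2 fold change of 0.48. Among the genes that the naming rule picked, calls at an adjusted p under 0.05 with no fold limit were lost, where the gene was tested, for PAU2, PAU12, DAN1, TIR4 and MFA2, and the cause was not tested. Single genes were not followed under the stricter thresholds, where ESS1 (adjusted p = 0.0109) is lost at 0.01. At this depth, 1.2-fold changes were recovered in part in simulated genes that were not low in counts.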

Other observations

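The tests of facing genes, snoRNA and gene pairs, combined trends, noncoding RNAs, shared reads and overlaps beside snoRNAs, and the expression of single-copy end genes were chosen only after the result was seen, as were the genes of the first 2 paragraphs that lie outside the fixed lists. The end list without gene copies was set in advance, but its use to weigh shared reads was chosen after. Of 11 tested noncoding RNAs with whole estimated counts other than snoRNAs, 7 rose and 2 fell in IAA, while the 15S rRNA of mitochondria and IRT1 did not pass the test (log2 fold changes -0.07 and 0.19). SCR1, the RNA of the signal recognition particle, rose 2.09-fold, from 15.5 ± 0.834 to 32.4 ± 3.7 CPM (mean ± SD, n = 2; edgeR adjusted p = 5.92e-05). RPR1, the RNA of RNase P, rose 2.29-fold, NME1, of RNase MRP, 2.38-fold, and SNR19, the U1 spliceosomal RNA, 2.19-fold. The U2 RNA LSR1 fell 1.24-fold, from 115 ± 7.17 to 93 ± 3.78 CPM (n = 2), the mitochondrial 21S rRNA, 21S_RRNA, fell 1.9-fold, from 11.2 ± 2.85 to 5.92 ± 2.25 CPM (n = 2; edgeR adjusted p = 0.0108), and the snoRNAs SNR83 and SNR86 fell 1.44-fold and 1.33-fold. The noncoding transcript SRG1 and the serine synthesis gene SER3, which is known to be repressed by its transcription, rose 1.59-fold and 2.32-fold. Their annotations overlap on the same strand (chromosome V, 322212 to 322762 and 322686 to 324095), so reads inside the overlap do not tell them apart, although both had whole counts. Rows of the ribosomal DNA, which share reads, were 2.11-fold higher for RDN37-1, 1.44-fold for RDN25-1 and 1.12-fold for RDN18-1.

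Reads of transposon genes, summed over 91 rows, rose 1.23-fold (edgeR adjusted p = 2.89e-04). Single YRF1 copies ranged from 1.37-fold lower for YRF1-6 to 10.6-fold higher for YRF1-7, where the DMSO libraries gave 12.4 and 5.17 CPM; all of these shared reads. Genes that face a snoRNA within 1000 bp on the opposite strand included PAM16, which fell 1.88-fold beside SNR37, RBA50 (1.53-fold) beside SNR84 and EFM3 (1.42-fold) beside SNR3. Others rose, among them POC4 beside SNR17B (log2 fold change 0.82) and KTR2 beside SNR42 (1.58-fold). Over all 27 such genes 7 rose and 11 fell, with a median log2 fold change of -0.04, at the 27.9 percentile of expression-matched random lists. Removing trends with expression, coding length and GC content took the median of the glycolysis genes from 0.40 to 0.01, that of glucose-repressed genes from 0.56 to 0.31, that of meiosis genes from 0.43 to 0.23 and that of ribosomal proteins from 0.17 to 0.24.

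Of the 32 genes just downstream of snoRNAs, CTO1, YDR042C, USE1 and FLX1 rose at least 2-fold, and only 0.04% of 10000 random lists matched on expression held as many, which argues against low expression as the cause. None of the 4 (0 genes) had decimals in its counts or a same-strand overlap with an annotated gene. The whole counts argue against reads shared with copies. Gene models have coding lengths, so overlap between longer transcripts could not be seen and stays open. A candidate explanation is transcription that runs on from the snoRNA into the next gene. Of the 27 facing genes 0 rose 2-fold, but with so few genes the difference was not past the threshold (Fisher's exact test, two-sided p = 0.118). Facing genes also serve as a comparison only if counting used the strand, which is not known. This explanation therefore stays open. Across the 14 snoRNA and gene pairs, which are not independent replicates, the changes correlated at Pearson r = 0.63 (permutation p = 0.012, 0.0233 after Benjamini-Hochberg over 6 relations) and Spearman rho = 0.81 (permutation p = 7.70e-04, adjusted 0.00249), at r = 0.63 and rho = 0.83 (permutation p = 0.0155 and 8.3e-04) for the 13 pairs outside introns, and at r = -0.02 and rho = 0.04 (both adjusted p = 0.942) for 22 facing pairs. Without the 2 snoRNAs farthest from the median, over 12 pairs, r was 0.48 (permutation p = 0.12), no longer past the threshold, and rho was 0.75 (permutation p = 0.00674). YDR042C and FLX1 were not among the pairs, since their snoRNAs, SNR47 and SNR68, were not tested.

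The rise near chromosome ends (median 0.20, 95% bootstrap interval 0.11 to 0.27) lay at the 99.95 percentile of random lists matched on expression. This argues against low expression alone as the cause for the whole list. The bootstrap intervals come from resampling genes, so they do not cover variation between cultures. Copies that share reads counted in them as separate genes. Without multi-copy families and genes with shared reads, 98 genes (median 0.13, 95% bootstrap interval 0.06 to 0.25) were still called at a preset correlation (camera adjusted p = 0.00948). With an estimated correlation they were not (camera adjusted p = 0.506, as for the whole list). The estimate for them was -0.0055, below the preset 0.01, which argues against correlation between genes as the reason. Those 98 genes lay at only the 93 percentile of random lists of like expression (random median 0.06, 95% of lists between -0.02 and 0.15), so for them low expression stays open, as do both causes acting together over the list. The 108 members with copies or shared reads had a median of 0.24, at the 99.13 percentile (95% of lists between 0.02 and 0.22). Only these members lay past the range of matched lists, so a part played by shared reads stays open. Removing trends with expression, coding length and GC content together lowered the median of the 200 coding members to 0.04 (95% bootstrap interval -0.02 to 0.14), at the 97.85 percentile of random lists of coding genes. Most of the rise may therefore go with these trends, and a remainder cannot be told apart from them, since the interval includes 0. An effect of Ess1 loss on chromosome ends, which the series title raises, stays open and untested.

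Of 44 noncoding RNAs with whole estimated counts, 30 rose and 4 fell, and the change decreased with length (Spearman rho = -0.52 across RNAs, permutation p = 2.40e-04; RNAs are not independent replicates). If the IAA libraries had taken up more RNA without poly(A) tails, all abundant ones should rise alike, yet 3 of the 11 at 10 CPM or more fell (LSR1, SNR83 and SNR86), which argues against this as the whole cause. LSR1 and SNR86 are long (1175 and 1004 bp), so their falls also go with length, while SNR83 is 306 bp. Ribosomal DNA rows with shared reads were left out of this test. Ribosomal DNA took 5.26% and 4.87% of the counts in DMSO and 7.02% and 6.16% in IAA. The share of snoRNA rows ranked the 4 libraries in the same order. Both go with more uptake of RNA without poly(A) tails, so a part played by it stays open. If the IAA libraries had taken up more short RNA, the change should decrease with length, as it did, and short coding genes should be higher too. Coding genes of up to 500 bp differed from longer ones of like expression by -0.13 on the log2 scale (95% bootstrap interval over the short genes -0.16 to -0.08). These are coding lengths, so the test may not reach RNA as short as most snoRNAs (SNR33 is 183 bp and SNR82 268 bp). More uptake of short RNA therefore stays open. A shift of both kinds at once was not tested. An effect of Ess1 loss or of IAA itself on noncoding RNA stays open and untested.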
